A study of Mus musculus with 63 samples.

How the data were processed

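Gene expression was measured by RNA sequencing of polyA RNA in 63 mouse libraries from intact and injured dorsal root ganglia, cultured ganglion neurons treated with siRNA, and brains and ganglia of Silc1 knockout and wild type animals. Per the labels, each ganglion library pooled ganglia from 3 animals, and the injury was a crush of the sciatic nerve at mid-thigh.

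The submitters' processing notes name StringTie for the gene models, RSEM for quantification and the genome build mm10. Per the file headers the models came from a StringTie 1.2.3 merge with a minimum length of 300 bases, a coverage of 0.5, an FPKM of 0.5 and an isoform fraction of 0.05. The deposited expected counts are RSEM estimates of reads per gene, made by the authors without scaling to depth. The deposited TPM values were made by the authors with RSEM within each library. The FPKM column was not used here. Each library table held the same 24373 gene rows. Gene names came from the annotation names in the merged models for 16876 rows and from an exon overlap of at least 50 bases on the same strand for 2568 rows, while 4929 rows matched no gene. Of the rows, 440 held several protein-coding genes, and 423 protein-coding symbols were split over more than 1 row. The model of Norris1 could not be told from the annotation, so its level is not analysed here.

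Each experiment was fitted on its own: the time course (19 libraries, 20266 genes tested), cultured neurons (9, 18091), brain (10, 16189), ganglia at day 4 (17, 18200) and ganglia at day 7 (8, 15441). Expected counts were rounded, filtered with filterByExpr (minimum count 10, minimum total count 15) and scaled by TMM. Genes were tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Folds are log2 with their standard error, and levels are mean TPM with SD. The common biological coefficient of variation was 0.27, 0.324, 0.182, 0.287 and 0.254 in the order above, with 12, 4, 7, 12 and 4 residual degrees of freedom. Library set entered the brain and day 4 models as a covariate. The sets (brain replicates 1 and 2 against 3 to 5, day 4 replicates 1 to 3 against 4 and 5) were inferred from the naming of the libraries, which may follow a batch of preparation or sequencing.

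Comparisons, 40 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Genes were named as the siRNA or knockout targets, as the 10 largest rises or falls of at least 5 CPM with groups that did not overlap, as up to 4 list members with the smallest p, as the 5 largest noncoding changes of at least 1 CPM, or as neighbours within 1 Mb of Silc1 and Sox11. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with a correlation estimated from the data. A list was called where both passed, and the p with the estimated correlation is printed. Members were also adjusted over the list alone.

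Injury scores were compared by exact two-sided permutation tests. Shared-control correlations were set against 50 simulations in which no gene changed, repeated for Silc1 and Sox11 siRNA with each control left out. Alternatives were DESeq2 1.42.0, RLE scaling, no filter and a stricter filter of 1 CPM, a fit with only the compared libraries, a replicate block, each library set alone, a joint fit of days 4 and 7, and each library left out in turn. Replicate numbers were checked as pairs from the correlation of same-numbered libraries after removal of group means. They may pair the libraries of the time course at day 7 (r 0.135 to 0.637), where sham 1 had an r of 0.154 with injured 2 and 0.135 with injured 1. Same-numbered libraries also correlated in the brain (0.14 to 0.435) and the WT (0.267 to 0.587) and KO (0.245 to 0.636) injury comparisons of day 4. Library set was not removed there and may give the same pattern. Brain WT 5 had an r of 0.594 with KO 4 and 0.291 with KO 5, and injured KO 1 of day 4 had 0.448 with sham KO 2 and 0.636 with sham KO 1. The other comparisons with 3 or more pairs were not taken as paired. In culture, with 2 pairs per comparison, all 5 same-numbered pairs of the experiment also correlated (0.297 to 0.439), so numbers may pair them as well. With group means removed, the 2 libraries of a group mirror each other, so these values are not independent. Silc1 siRNA 2 and Norris1 siRNA 3 had the same r of 0.306 as Silc1 siRNA 1 and Norris1 siRNA 1. The blocked values are given with the alternatives.

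The methods were tested on simulated data with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in libraries of each design. Of the genes changed 2-fold, 47.8%, 37.3% and 43.3% were recovered in the time course at days 1, 4 and 7, 7.5% with Silc1 siRNA, 79.1% in brain, 41.8% and 38.8% in the sham and injury genotype comparisons of day 4 and 14.9% in the injury genotype comparison of day 7. In the same order, 9, 7, 8, 7, 13, 3, 5 and 5 genes left unchanged passed the test too. With 1 Sox11 siRNA library 45.5% of genes changed 4-fold were recovered. Duplicated libraries were looked for within groups, and none were found (chi-square per gene of at least 4.25 between replicates).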

Results

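RNA was sequenced from 63 mouse libraries in a study of long noncoding RNAs in nerve regeneration. Dorsal root ganglia (DRG) hold the cell bodies of sensory neurons whose peripheral axons run in the sciatic nerve and can regrow after a crush. The time course held 19 libraries of intact ganglia. Of these, 3 were from naive animals, 2, 3 and 3 were taken 1, 4 and 7 days after a sciatic nerve crush, and 3, 2 and 3 were taken 1, 4 and 7 days after a sham operation. Cultured DRG neurons gave 9 libraries: 3 with control small interfering RNA (siRNA), 2 with siRNA against the long noncoding RNA Silc1, 2 against the long noncoding RNA Norris1, and 1 each against the transcription factors Sox11 and Atf3. The Silc1 knockout (KO) was set against wild type (WT) in 10 brain libraries (5 and 5), in 17 ganglion libraries at day 4 (WT 4 injured and 3 sham, KO 5 injured and 5 sham) and in 8 ganglion libraries at day 7 (2 per group). Each ganglion library was a pool from 3 animals. The labels do not state that the neuron libraries came from separate cultures, so p-values there measure the spread between libraries, which may be technical.

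Depth differed between experiments. Total estimated counts ran from 10.9 to 55.3 M per library in the time course (median 27.2 M), 9.7 to 65.2 M in culture (23.8 M), 6.21 to 41.4 M in brain (23.8 M), 5.17 to 29.9 M at day 4 (14.3 M) and 3.36 to 13.3 M at day 7 (5.57 M). Silc1 is the published name of the long intergenic RNA annotated as Gm9866. Its reads were assigned to the model MSTRG.4509 on the minus strand of chromosome 12 of mm10, from 27140189 to 27160779, with 7 exons and 3409 exonic bases. A single-exon model, MSTRG.4508, with the same annotation lay just 3′ of it, from 27139420 to 27140132. Sox11, a SoxC transcription factor gene, lay on the same strand from 27334264 to 27347629.

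The targeted genes were examined in every sample first. In brain, Silc1 stood between 26.8 and 39.5 TPM in the WT libraries (32.5 ± 5.68, SD, n = 5) and between 0 and 0.34 TPM in the KO libraries (0.096 ± 0.141, n = 5). In day 7 ganglia it stood at 6.84 to 21.9 TPM in the 4 WT libraries and at 0 to 0.23 TPM in the 4 KO libraries. In day 4 ganglia the WT libraries held 2.8 to 25.4 TPM, and 4 of the 10 libraries labelled KO held Silc1 reads. These were the libraries labelled KO injury 1 (3.49 TPM), KO injury 3 (3.3), KO sham 1 (3.62) and KO sham 3 (1.23), while the 6 others had at most 0.05 TPM. The Silc1 siRNA libraries held 0.13 and 0.46 TPM against 1.63, 0.73 and 1.21 TPM with control siRNA. These levels rest on few reads, with 7 and 12 expected counts of Silc1 against 14, 21 and 62. The 0.13 TPM is that of Silc1 siRNA library 1, where the 10 most abundant genes took 55.4% of the counts, which lowers the TPM of the other genes. Sox11 in the Sox11 siRNA library stood at 21.2 TPM, within the 14.8 to 53.7 TPM of the controls. That library is replicate 1, and control 1 held 53.7 TPM, so the range does not show that Sox11 was unreduced. Atf3 in the Atf3 siRNA library stood at 184 TPM, below the 306 to 570 TPM of the controls.

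**Figure D1:**
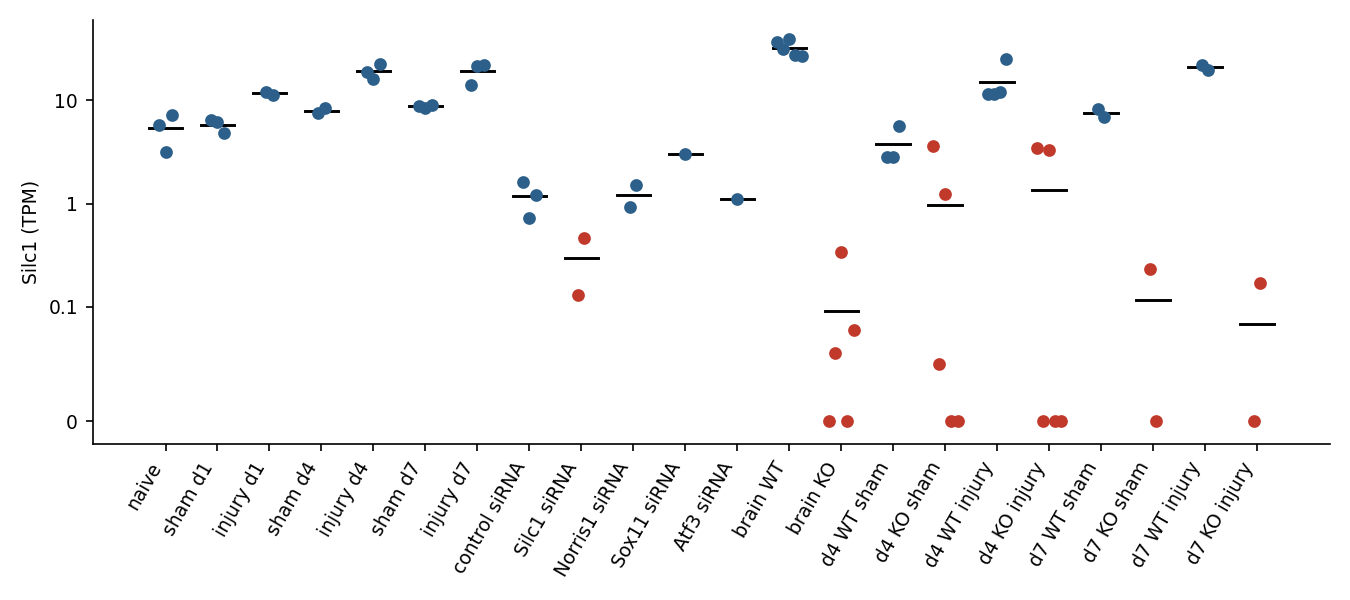
Silc1 level in every library, in TPM on a symmetric log axis that is linear below 0.1, by group; circles are libraries and bars are group means. Brain WT libraries sit between 26.8 and 39.5 TPM and brain KO libraries at or below 0.34 TPM, while 4 day 4 ganglion libraries labelled KO sit between 1.23 and 3.62 TPM.

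The time course asked which transcripts of the ganglion change after the axons of its neurons are crushed. At day 1, genes of the neuronal injury response rose. Atf3, a stress-induced transcription factor and a standard marker of injured sensory neurons, averaged 273 ± 97.9 TPM (SD, n = 2) after injury and 29 ± 15.8 TPM after sham (n = 3), a log2 fold change of 3.15 ± 0.41 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.00281). Among the largest rises with a symbol and groups that did not overlap were those of Sprr1a, a small proline-rich protein linked to axon outgrowth (3.6 ± 0.58), Atf3, Gadd45a, a stress and DNA damage gene (2.44 ± 0.29), and the orphan receptor Gpr151 (2.44 ± 0.38). Sox11 rose from 3.33 ± 1.12 to 13.9 ± 2.08 TPM (1.99 ± 0.32). Of 37 measured regeneration-associated genes, 21 rose and 16 did not pass the test, and 28 rose when adjusted over the list alone (median log2 fold change 1.34; camera adjusted p = 0.0349 with an estimated correlation). Of 16 SoxC and partner transcription factors 5 rose, among them Jun (1.59 ± 0.26) and Stat3 (0.75 ± 0.14), and 8 rose and 1 fell adjusted over the list alone (adjusted p = 0.0731 with an estimated correlation, Benjamini-Hochberg, camera). Il6 (2.88 ± 0.42) and the macrophage growth factor Csf1 (1.48 ± 0.25) rose too. Of 16 interferon-stimulated genes 4 rose, including Ifit1 (1.83 ± 0.35), Usp18 (1.52 ± 0.30) and Stat2 (0.91 ± 0.16), and 8 rose adjusted over the list alone (camera adjusted p = 0.128 with an estimated correlation).

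The largest falls at day 1 among genes with groups that did not overlap began with Ptgds, a prostaglandin D synthase. It stood at 269 ± 11.8 TPM after injury and 2010 ± 1090 TPM after sham (−3.01 ± 0.66), followed by Fgfbp1 (−2.57 ± 0.56), the retinoic acid enzyme Aldh1a2 (−2.43 ± 0.48), the transporter Slc6a20a (−2.39 ± 0.47) and Igf2 (−2.06 ± 0.42). Oprl1, the nociceptin receptor (−0.75 ± 0.14), and Chrna6, a nicotinic receptor subunit (−0.72 ± 0.15), fell too. Of 12 fibroblast and collagen genes 9 fell adjusted over the list alone (median −0.80; camera adjusted p = 0.179 with an estimated correlation). Silc1 averaged 11.7 ± 0.438 TPM after injury and 5.8 ± 0.851 after sham, a log2 fold change of 0.75 ± 0.22 that did not pass the test (edgeR, Benjamini-Hochberg adjusted p = 0.141). In all, 166 of 20266 genes passed (152 up, 14 down), and DESeq2 called 713. The count was 4 without injury library 2, 62 and 56 without sham libraries 2 and 3, and 0 when only these 5 libraries entered the fit.

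At day 4, neuropeptide and axon growth genes were among those that rose. Lipn, a lipase gene, rose from 1.39 ± 0.905 to 18.4 ± 5.83 TPM (log2 fold change 4.25 ± 0.44), followed by Anxa10, an annexin (4.13 ± 0.59), and the neuropeptide Npy (3.56 ± 0.51; 18.2 ± 13.1 to 199 ± 30.4 TPM). Sprr1a rose to 1010 ± 146 TPM (n = 3) from 106 ± 75.7 (n = 2), a log2 fold change of 3.33 ± 0.57 (edgeR, Benjamini-Hochberg adjusted p = 0.0073). Atf3 rose by 3.14 ± 0.46 and Sox11 by 1.93 ± 0.35. Silc1 rose from 7.95 ± 0.608 to 19.3 ± 3.15 TPM, a log2 fold change of 1.54 ± 0.23 (edgeR, Benjamini-Hochberg adjusted p = 0.00313). Of 37 regeneration-associated genes 19 rose, with 28 adjusted over the list alone (median 1.5; camera adjusted p = 0.0238 with an estimated correlation). Of 16 neuropeptides 4 rose, including galanin, Gal (196 ± 134 to 1100 ± 139 TPM; 2.56 ± 0.40), neurotensin, Nts (2.24 ± 0.24), and corticotropin-releasing hormone, Crh (2.24 ± 0.39), and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.227 with an estimated correlation). Of 19 axon growth and microtubule genes 4 rose, among them the growth cone protein Gap43 (1.24 ± 0.19), the tubulin Tubb6 (2.45 ± 0.32) and the stathmin Stmn4 (1.90 ± 0.28), with 7 adjusted over the list alone (camera adjusted p = 0.127 with an estimated correlation).

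Among the cells around the neurons at day 4, 1 of 17 macrophage markers rose, the mannose receptor Mrc1 (1.64 ± 0.32), with 9 adjusted over the list alone (median 1.16; camera adjusted p = 0.23 with an estimated correlation). Of 15 cytokines and chemokines 3 rose, Il6, Csf1 and the monocyte attractant Ccl7 (1.74 ± 0.37), with 4 adjusted over the list alone (camera adjusted p = 0.127 with an estimated correlation). The 5 largest falls among genes with groups that did not overlap were those of Serpina1e (−1.27 ± 0.23), Tpd52l1 (−1.14 ± 0.21), Gm16551 (−1.13 ± 0.23) and both subunits of the serotonin-gated channel, Htr3b (−1.12 ± 0.20) and Htr3a (148 ± 21.3 to 68.8 ± 15.8 TPM; −1.03 ± 0.20). Of 31 nociceptor channels and receptors 1 fell, with 5 adjusted over the list alone (median −0.42; camera adjusted p = 0.221 with an estimated correlation). Noncoding genes that rose included 4930412L05Rik (3.71 ± 0.59), AC121603.3 (3.50 ± 0.46) and Gm4208 (3.00 ± 0.40), and Gm19461 fell (−0.72 ± 0.16). The test called 276 genes (243 up, 33 down), and DESeq2 called 558. The count was 6 without sham library 3, 74 without sham library 1, 160 and 105 without injury libraries 1 and 3, and 171 when only these 5 libraries entered the fit.

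At day 7, genes of injured neurons rose as well. Lipn rose by 3.30 ± 0.35, Npy by 2.82 ± 0.41 and Sprr1a by 2.63 ± 0.47 (173 ± 59.2 to 1090 ± 366 TPM, n = 3 and 3; edgeR, Benjamini-Hochberg adjusted p = 0.00968). Silc1 rose from 8.77 ± 0.229 to 19.3 ± 4.51 TPM (1.24 ± 0.20), Sox11 from 4.13 ± 0.317 to 13.6 ± 3 TPM (1.76 ± 0.30) and Atf3 from 65.8 ± 7 to 291 ± 92 TPM (2.09 ± 0.37). Of 37 regeneration-associated genes 20 rose, with 28 adjusted over the list alone (median 1.19; camera adjusted p = 0.083 with an estimated correlation). Of 19 axon growth genes 4 rose, Tubb6 (1.65 ± 0.27), Stmn4 (1.19 ± 0.24), the actin bundler Fscn1 (1.12 ± 0.23) and Gap43 (0.78 ± 0.16), with 6 adjusted over the list alone (camera adjusted p = 0.274 with an estimated correlation). Of 17 macrophage markers 2 rose, including Trem2, a lipid receptor of macrophages (1.45 ± 0.34), with 15 adjusted over the list alone (median 1.01; camera adjusted p = 0.274 with an estimated correlation). The muscle genes Tnnt1 (3.27 ± 0.76) and Igfn1 (3.08 ± 0.62) rose, and 10 of 11 skeletal muscle markers rose adjusted over the list alone (median 4.90; camera adjusted p = 0.351 with an estimated correlation). Muscle genes were also high in naive libraries, and whether the muscle transcripts come from the ganglion was not tested. Trem2 and Tnnt1 were not called with the replicate block.

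Falls at day 7 included Serpina1e (−1.52 ± 0.21), Tpd52l1, Gng8, a G protein gamma subunit (45 ± 9.82 to 18.4 ± 2.77 TPM; −1.24 ± 0.16), Htr3a (−1.14 ± 0.18) and Htr3b (−1.11 ± 0.18). Of 31 nociceptor channels and receptors 1 fell, with 8 adjusted over the list alone (median −0.42; camera adjusted p = 0.351 with an estimated correlation). The noncoding genes AC121603.3 (2.88 ± 0.38), Gm47903 (2.71 ± 0.47) and Gm31831 (2.64 ± 0.50) rose and Gm19461 fell (−1.05 ± 0.14). The test called 297 genes (226 up, 71 down), and DESeq2 called 811. The count was 106 and 125 without injury libraries 2 and 3, 80 and 89 without sham libraries 2 and 3, and 161 when only these 6 libraries entered the fit.

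**Figure D2:**
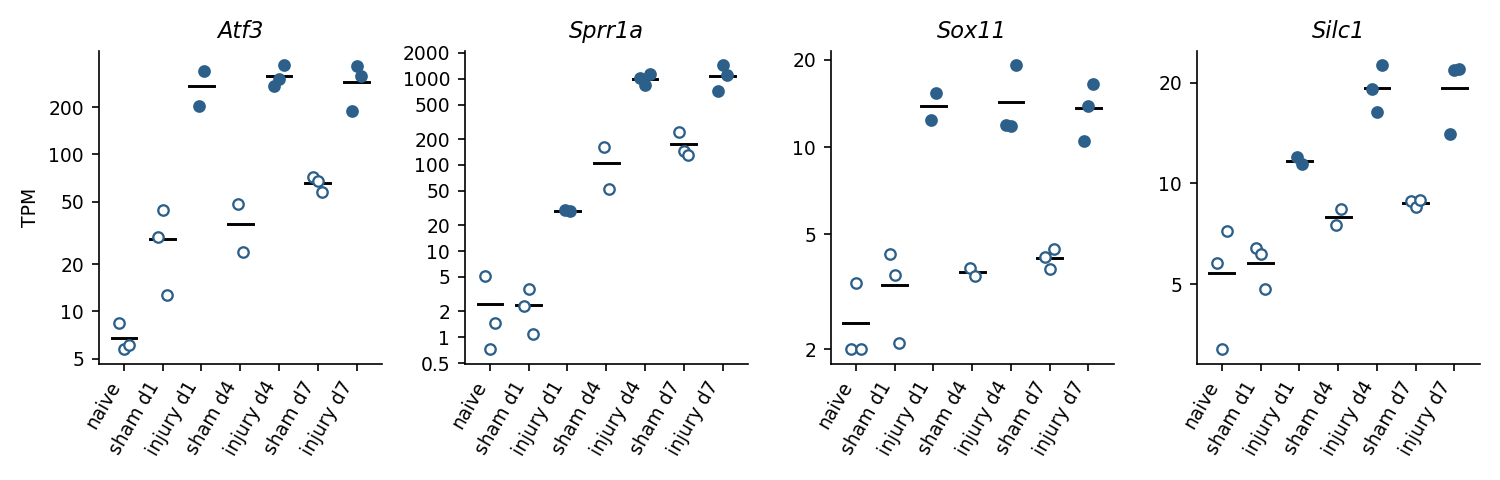
TPM of Atf3, Sprr1a, Sox11 and Silc1 in every time course library on log axes, by day after sciatic nerve crush (filled) or sham (open), with naive libraries at the left; bars are group means. Silc1 averages 19.3 TPM in injured ganglia at days 4 and 7 against 7.95 and 8.77 TPM after sham, and Sprr1a stands at 106 and 173 TPM in the shams of days 4 and 7 against 2.45 TPM in naive ganglia.

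The responses of the days shared more genes than independent lists would. Days 1 and 4 shared 75 rising genes (1.82 for independent lists), days 4 and 7 shared 158 rising (2.71) and 23 falling genes (0.116), and 60 genes rose at all 3 days, Atf3, Sox11 and Sprr1a among them. In tests of the difference itself, 1 gene differed between the responses of days 4 and 1 (edgeR, unadjusted p under 0.05 in 1749 genes, DESeq2 98). This was MSTRG.6303, an unannotated transcript of 2 exons on the plus strand of chromosome 14, from 32115354 to 32120379 (edgeR, Benjamini-Hochberg adjusted p = 0.0297). It was listed at 0 in both day 4 sham libraries and at 2.57 to 4.53 TPM in the 3 injured libraries of that day, and at 8.04 to 11.5 TPM in the day 1 shams and 2.17 and 2.82 TPM in the injured libraries of day 1, so that a lower level after injury at day 1 makes up part of the difference. Its call was lost with the replicate block and without 8 of the 10 libraries in turn, and without day 1 sham library 1 the count was 4. Macrophage markers responded more at day 4 than at day 1 in 13 of 17 genes adjusted over the list alone, and interferon-stimulated genes less in 6 of 16 (camera adjusted p = 0.284 with an estimated correlation for both lists). Between days 7 and 4, edgeR called 0 genes (418 at an unadjusted p under 0.05, DESeq2 20), and 1 without injured library 1 of day 7.

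Sham-operated ganglia were compared with naive ganglia as the background of the crush. At day 1 the largest falls included genes of the seminal vesicle and of muscle, which were high in the naive libraries. Svs6, a seminal vesicle secretory protein, stood at 194 ± 245 TPM in naive ganglia and 0.877 ± 0.891 after sham (n = 3 and 3), and Svs4 in the naive libraries stood at 912, 49 and 127 TPM. The muscle myosin light chain Mylpf stood at 148 ± 185 TPM in naive ganglia and 4.03 ± 1.33 after sham (−5.38 ± 1.18), and 8 of 11 skeletal muscle markers fell, 11 adjusted over the list alone (camera adjusted p = 0.918 with an estimated correlation). The synaptic vesicle gene Syn1 fell (−0.97 ± 0.22). Of 31 nociceptor genes 6 fell and 1 rose, and of 14 pan-neuronal markers 3 fell (in each list 6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.918 with an estimated correlation for both). Etnppl, a lyase that breaks down phosphoethanolamine, rose (2.36 ± 0.36), and Atf3 rose from 6.76 ± 1.48 to 29 ± 15.8 TPM (1.97 ± 0.39; edgeR, Benjamini-Hochberg adjusted p = 0.0334). The test called 1353 genes (273 up, 1080 down), and DESeq2 called 2981. The count was 2 without sham library 2, 37 without sham library 3, 30, 503 and 3108 without naive libraries 2, 1 and 3, and 0 when only these 6 libraries entered the fit.

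At days 4 and 7 some neuronal injury genes stood higher in the shams than in naive ganglia. At day 4, Sprr1a stood at 106 ± 75.7 TPM against 2.45 ± 2.39 (5.13 ± 0.60; edgeR, Benjamini-Hochberg adjusted p = 0.00288), and Gpr151 rose by 2.67 ± 0.42. At day 7, Sprr1a stood at 173 ± 59.2 TPM (5.87 ± 0.59), and the gastrin receptor Cckbr (4.71 ± 0.47), the endopeptidase Ecel1 (4.06 ± 0.55), Npy (3.78 ± 0.50) and Atf3 (3.04 ± 0.40; 65.8 ± 7 against 6.76 ± 1.48 TPM) rose. Of 37 regeneration-associated genes 3 rose at day 4 and 9 at day 7, with 8 at day 4 and 18 up and 1 down at day 7 adjusted over the list alone (camera adjusted p = 0.966 and 0.476 with an estimated correlation). Silc1 did not pass at either day (0.46 ± 0.23 and 0.63 ± 0.20; edgeR, Benjamini-Hochberg adjusted p = 0.527 and 0.141). Svs6 and Svs4 fell at day 7 as at day 1 (−9.48 ± 1.27 and −8.57 ± 1.30). The test called 11 genes at day 4 (10 up, 1 down; DESeq2 470) and 51 at day 7 (34 up, 17 down; DESeq2 1022). Without 1 library, the day 4 count was 3 (sham 1), 6 (naive 1) and 345 (naive 3), the day 7 count was 20, 22 and 18 (sham 1, 2 and 3), 499 (naive 1) and 678 (naive 3), and with only the compared libraries they were 0 and 1.

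The siRNA experiment asked what cultured sensory neurons express when these regulators are reduced. With Silc1 siRNA, Silc1 itself had a log2 fold change of −0.73 ± 0.57 and Sox11 of 0.51 ± 0.62 (edgeR, Benjamini-Hochberg adjusted p = 1 for both, n = 2 and 3). For Silc1 it was −1.28 without Silc1 siRNA library 1 and −0.15 without library 2. In Silc1 siRNA library 1, the 10 most abundant genes took 55.4% of the counts and Gm42418, a gene over ribosomal RNA sequence, took 10.6%, against 4.67 to 6.35% and 0.0306 to 0.56% in the other 8 libraries. That lowers the TPM of every other gene, so Sox11 stood at 8.89 TPM there and at 22.2 TPM in the other Silc1 siRNA library, and without library 1 the log2 fold change of Sox11 was −0.49. The neighbouring gene Rnf144a, an E3 ubiquitin ligase, had a log2 fold change of 0.02. Macrophage markers (17 genes, median −2.42) and Schwann cell markers (14 genes, median −0.60) stood lower with the preset correlation of camera only (adjusted p = 0.917 with an estimated correlation for both), and 0 members of either list passed adjusted over the list alone. For Silc1 siRNA edgeR called 0 genes (613 at an unadjusted p under 0.05, DESeq2 4), and for Norris1 siRNA also 0 (196 unadjusted, DESeq2 2). The Norris1 transcript itself is not analysed here.

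The Sox11 and Atf3 siRNAs had 1 library each, which was assumed to vary like the other groups. With Sox11 siRNA, Ifit1, an interferon-induced RNA-binding protein, stood at 33 TPM against 1.96 ± 0.272 TPM in the controls (3.98 ± 0.28; edgeR, Benjamini-Hochberg adjusted p = 0.0151). It was the gene called, and edgeR called 0 without any one of the 3 controls (436 at an unadjusted p under 0.05 with all controls, DESeq2 22). The Ifit1 and list results for this siRNA rest on 1 library with no replicate of its own. Of 16 interferon-stimulated genes 13 rose adjusted over the list alone, among them Usp18 (4.27 ± 0.59) and Ifi44 (4.56 ± 0.64), with a median log2 fold change of 2.28 (camera adjusted p = 0.0724 with an estimated correlation). Sox11 itself had a log2 fold change of −0.64 ± 0.82, which ran from −0.97 without control 3 to −0.11 without control 1. Control 1 carries the replicate number of the Sox11 siRNA library and held 53.7 TPM of Sox11, against 21.2 TPM in that library. With Atf3 siRNA, Atf3 had a log2 fold change of −1.35 ± 0.40 (edgeR, Benjamini-Hochberg adjusted p = 1), and 9 of the 16 interferon-stimulated genes rose adjusted over the list alone (median 1.15; camera adjusted p = 0.248 with an estimated correlation), with Ifit1 at 13.7 TPM. For Atf3 siRNA edgeR called 0 genes (631 at an unadjusted p under 0.05, DESeq2 46).

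Whether Silc1 siRNA moved the genes that Sox11 siRNA moved was tested across genes. The log2 fold changes of the 18091 genes had a Pearson r of 0.18 between both siRNAs, where 50 simulations of unchanged groups sharing the 3 controls gave a mean r of 0.23 and at most 0.27. The covariance was 0.148, equal to the simulated 0.148. Over the 9915 genes with a mean of at least 10 CPM r was 0.12 (simulated 0.3) and the covariance 0.018 (simulated 0.044). For Silc1 and Norris1 siRNA r was 0.19 over all genes (simulated 0.37). The simulations gave more correlation than was seen here, so a match to them does not show that the responses are unrelated. Without control 1 the r of Silc1 and Sox11 siRNA was 0.29 over all genes. Simulations with the other 2 controls gave a mean of 0.28 and at most 0.31. For Sox11 and Atf3 siRNA r was 0.34 (simulated 0.21) and the covariance 0.303 (simulated 0.176). Independent lists would share 0 calls in every pair. The 3 controls are too few to give each siRNA controls of its own, so part of any excess may come from the shared controls. The simulations also treat libraries as independent, while same-numbered siRNA libraries deviated together (r 0.297 to 0.439) and the Sox11 and Atf3 libraries are both replicate 1, so that an excess between them may come from the shared number. Genes are not independent replicates here.

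The Silc1 knockout brains were compared with WT brains. Silc1 fell by 8.84 ± 0.32 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 1.94e-07), and was lower in 5 of 5 KO libraries than in any WT library. Within library sets inferred from the naming of the libraries, its log2 fold change was −9.33 in set 1 and −8.57 in set 2. The adjacent model MSTRG.4508 was at 0 in all 5 KO libraries and at 14.8 ± 3.8 TPM in WT (n = 5), at least 172-fold lower against a floor of 3 counts over the KO group. These 2 were the genes called (edgeR, 525 at an unadjusted p under 0.05, DESeq2 4). The count was 1 with the replicate block and 1 within each library set. Sox11 stood at 5.41 ± 1.17 TPM in KO and 6.96 ± 1.63 in WT, a log2 fold change of −0.15 ± 0.12 (edgeR, Benjamini-Hochberg adjusted p = 0.855), with 0.03 in set 1 and −0.27 in set 2. Its other neighbours within 1 Mb, Rnf144a (0.06), the interferon-induced Rsad2 (0.03) and the nucleotide kinase Cmpk2 (−0.02), had folds near 0. Immediate early genes (13 genes, median 0.39), with Egr1 at 213 TPM in KO and 171 in WT, and striatal markers (7 genes, median −0.85), with the dopamine receptor Drd2 at −1.22, stood apart with the preset correlation of camera only (adjusted p = 0.746 with an estimated correlation for both). In both lists 0 genes passed adjusted over the list alone, and striatal markers had the opposite sign in set 1.

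The day 4 genotype experiment repeated the crush in WT animals. The neuronal injury genes rose again, from lower sham levels than in the time course. Atf3 rose from 9.91 ± 1.21 TPM (n = 3) to 316 ± 47.9 (n = 4), a log2 fold change of 4.89 ± 0.48 (edgeR, Benjamini-Hochberg adjusted p = 1.44e-05). Sprr1a rose from 3.85 ± 4.2 to 909 ± 98.4 TPM (7.61 ± 1.08), Npy from 1.27 ± 1.11 to 152 ± 10.6 (6.61 ± 0.54), Gal from 40.9 ± 3.8 to 923 ± 157 (4.44 ± 0.27) and Sox11 from 2.11 ± 0.688 to 20.6 ± 2.03 (3.54 ± 0.38). Anxa10 was at 0 in all 3 sham libraries and at 9.57 to 21 TPM after injury, at least 115-fold higher against a floor of 3 counts over the sham group. Of 36 regeneration-associated genes 25 rose, with 29 adjusted over the list alone (median 1.88; camera adjusted p = 0.00446 with an estimated correlation). Of 19 axon growth genes 4 rose, among them Gap43 (1.80 ± 0.16) and Tubb6 (2.73 ± 0.30), with 4 adjusted over the list alone (camera adjusted p = 0.0235 with an estimated correlation). Of 17 macrophage markers 2 rose, Mrc1 (1.78 ± 0.40) and Adgre1, the F4/80 antigen (1.57 ± 0.38), with 8 adjusted over the list alone (camera adjusted p = 0.435 with an estimated correlation). Of 31 nociceptor genes 2 fell, Mrgprx1, an itch receptor (−0.80 ± 0.15), and Chrna6 (−0.97 ± 0.23), with 5 adjusted over the list alone (camera adjusted p = 0.45 with an estimated correlation). Silc1 stood at 15.1 ± 6.84 TPM after injury and 3.76 ± 1.64 after sham, a fold of 1.91 ± 1.24 that did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.635). The WT groups did not overlap (11.5 to 25.4 against 2.8 to 5.65 TPM). The fit estimates the spread of Silc1 also from libraries labelled KO, which ran from 0 to 3.62 TPM after sham and 0 to 3.49 after injury. The test therefore does not show that a rise is absent in WT. The test called 464 genes (406 up, 58 down; DESeq2 747), 837 in set 1, 0 in set 2, which held 1 injured and 1 sham WT library, and 295 and 296 without sham libraries 2 and 3.

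Across both injury experiments, all of the 272 time course day 4 calls that could be tested had the same sign in the WT day 4 comparison, and 181 of them (66.5%) were called there too. Of the rising genes 173 were shared (5.34 for independent lists) and of the falling genes 8 (0.106). Across the 18119 genes tested in both, which are not independent replicates, the log2 fold changes had a Pearson r of 0.537.

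In ganglia of libraries labelled KO, the same neuronal genes rose at day 4. Atf3 rose from 14.5 ± 12.7 to 368 ± 88.3 TPM (4.92 ± 0.38, n = 5 and 5), Sprr1a by 7.33 ± 0.83, Npy by 6.96 ± 0.42, Gal by 4.13 ± 0.21 and Sox11 from 4 ± 2.7 to 33.3 ± 13.9 TPM (2.98 ± 0.29; edgeR, Benjamini-Hochberg adjusted p = 4.88e-06). Of 36 regeneration-associated genes 25 rose, with 28 adjusted over the list alone (median 1.48; camera adjusted p = 0.00784 with an estimated correlation). Of 17 macrophage markers 13 rose, among them Mrc1 (1.75 ± 0.33) and the complement component C1qb (1.59 ± 0.35), with 17 adjusted over the list alone (camera adjusted p = 0.313 with an estimated correlation). Of 31 nociceptor genes 8 fell, including Mrgprx1 (−1.16 ± 0.13), the irritant channel Trpa1 (−1.05 ± 0.19), Grik1 (−0.87 ± 0.15) and the itch receptor Mrgpra3 (−0.86 ± 0.15), with 16 adjusted over the list alone (median −0.69; camera adjusted p = 0.313 with an estimated correlation). Somatostatin, Sst, fell too (−1.56 ± 0.31). The test called 796 genes (590 up, 206 down; DESeq2 1303), 1277 in set 1 and 24 in set 2, 406 without the libraries labelled KO that held Silc1 reads, and 514 and 524 without injured libraries 2 and 5. WT and KO shared 335 rising (13.2 for independent lists) and 30 falling genes (0.656).

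The difference between the KO and WT responses at day 4 was tested directly. For this interaction edgeR called 0 genes (421 at an unadjusted p under 0.05, DESeq2 4) and 1 within set 1, and Sox11 had a difference of −0.56 ± 0.44. The 16 interferon-stimulated genes had a median difference of 0.71 with 0 genes adjusted over the list alone (camera adjusted p = 0.573 with an estimated correlation). An injury score, the mean log2 level of 185 genes that rose minus that of 11 that fell at least 2-fold in the time course at day 4, stood at 2.26 ± 0.31 in injured WT (n = 4) and 1.78 ± 0.88 in injured KO libraries (n = 5). The difference of −0.48 had an exact two-sided permutation p of 0.381 (smallest possible 0.00794). After sham the score stood at −1.22 ± 0.59 in WT (n = 3) and −1.43 ± 0.36 in KO (n = 5), an exact permutation p of 0.571 (smallest possible 0.0179). Within set 1 the differences were −0.83 (exact p = 0.3) and −0.41 (exact p = 0.6, smallest possible 0.1 for both). Without the libraries labelled KO that held Silc1 reads, the injured difference was 0.15 (exact p = 0.457), and without WT sham library 2 the sham difference was 0.07.

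**Figure D3:**
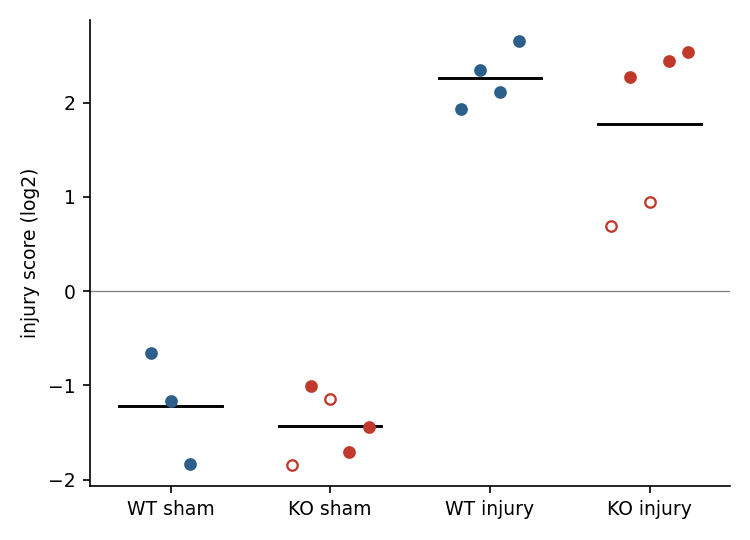
Injury score of every day 4 ganglion library (log2 units, 185 rising minus 11 falling genes of the independent time course), by genotype label and operation; circles are libraries, open for libraries labelled KO that held Silc1 reads, and bars are means. Injured libraries sit between 0.69 and 2.65 and sham libraries below 0 in both genotypes.

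The KO and WT ganglia of day 4 were compared directly, after sham and after injury. Sox11 did not pass: after sham it stood at 4 ± 2.7 TPM in KO and 2.11 ± 0.688 in WT (log2 fold change 0.56 ± 0.34; 0.50 in set 1 and 0.77 in set 2), and after injury at 33.3 ± 13.9 and 20.6 ± 2.03 TPM (0.00 ± 0.28; −0.05 and 0.23). The folds come from counts, which after injury averaged 73.7 ± 28.9 CPM in KO and 71.3 ± 3.07 in WT, while TPM also divide by the effective length that RSEM gave Sox11 in each library, on average 3440 bases in injured KO and 5100 in injured WT. Why these lengths differ was not tested. Silc1 had folds of −2.44 ± 1.24 and −3.72 ± 1.12 (edgeR, Benjamini-Hochberg adjusted p = 0.411 and 0.318), which the libraries labelled KO with Silc1 reads hold down. In set 1 the folds were −1.33 and −2.48, and in set 2 all 4 KO libraries were at 0 and the 2 WT libraries at 5.65 and 25.4 TPM. The neighbour Rsad2 stood at 4.68 ± 1.54 TPM in KO and 12 ± 6.36 in WT after sham (−1.64 ± 0.43; edgeR, Benjamini-Hochberg adjusted p = 0.252). Nociceptor genes stood higher in KO after sham (31 genes, median 0.38), for example the sodium channel Scn11a at 165 ± 67.3 against 86.5 ± 22.5 TPM, with 2 adjusted over the list alone (camera adjusted p = 0.421 with an estimated correlation). Macrophage markers (17 genes, median −0.95) stood lower, with 0 adjusted over the list alone (camera adjusted p = 0.509 with an estimated correlation), and so did interferon-stimulated genes (16 genes, median −0.76), with 8 (adjusted p = 0.421 with an estimated correlation). All 3 lists had the opposite sign in set 2, which held 1 WT sham library.

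In both direct comparisons edgeR called 0 genes (after sham 2359 at an unadjusted p under 0.05, DESeq2 160, after injury 1741 and 74). The 2 library sets gave different counts: 6516 after sham and 4248 after injury in set 1, which held 2 and 3 WT libraries, and 0 in set 2, which held 1 WT library of each. Without WT sham library 5 the sham count was 2136 and without WT sham library 2 it was 2. The libraries labelled KO that held Silc1 reads were all in set 1, and without them 1 gene was called after sham and 1 after injury. The share of counts in mitochondrial genes moved with genotype in set 1, at 6.06 to 8.14% in WT and 2.54 to 4.19% in KO, and not in set 2, at 4.63 to 5.79% and 4.75 to 9.62%. Within set 1, the sham and injury folds correlated across 15285 genes (Pearson r = 0.66).

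**Figure D4:**
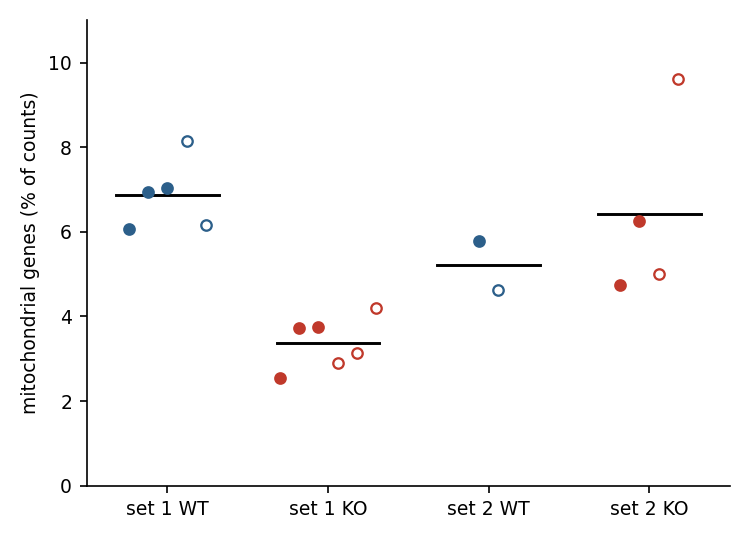
Percent of counts in mitochondrial genes in every day 4 ganglion library, by library set and genotype label; filled circles are injured and open circles sham libraries, and bars are means. In set 1 all WT libraries (6.06 to 8.14%) lie above all libraries labelled KO (2.54 to 4.19%), and in set 2 the ranges overlap.

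At day 7, with 2 libraries per group, injury genes rose in both genotypes. In WT, Lipn rose from 1.11 ± 0.339 to 19 ± 1.51 TPM (5.68 ± 0.40; edgeR, Benjamini-Hochberg adjusted p = 0.00237), Gal from 94.8 ± 15.9 to 832 ± 5.13 TPM (3.08 ± 0.23) and Sox11 from 3.14 ± 1.68 to 17.5 ± 0.417 TPM (2.45 ± 0.23). In KO, Sprr1a rose from 0.91 ± 0.453 to 625 ± 265 TPM (9.18 ± 1.23), Gal by 3.96 ± 0.24, Atf3 by 5.09 ± 0.74 and Sox11 from 2.71 ± 0.481 to 28.2 ± 7.83 TPM (3.37 ± 0.23; edgeR, Benjamini-Hochberg adjusted p = 0.00113). Npy was at 0 in both KO sham libraries and at 224 and 326 TPM in the injured ones, at least 382-fold higher against the floor of 3 counts over the sham group. Of 35 regeneration-associated genes 7 rose in WT and 14 in KO, with 26 and 30 adjusted over the list alone (camera adjusted p = 0.275 and 0.156 with an estimated correlation). The test called 36 genes in WT and 56 in KO, all up, with 28 shared (0.131 for independent lists). DESeq2 called 148 and 147, the fit with day 4 libraries 113 and 130, and a test with no filter on low counts 110 and 130, while RLE scaling gave 19 in WT. The WT count was 3 without injured library 1 or 2, 6 without sham library 1 and 0 without sham library 2, and the KO count was 22 without injured library 1 and 6 without sham library 2.

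The KO and WT ganglia of day 7 were compared with 2 libraries per group. Silc1 was lower in each KO library than in any WT library, and had a log2 fold change of −6.54 ± 0.88 after sham and −7.69 ± 0.83 after injury (edgeR, Benjamini-Hochberg adjusted p = 0.822 and 0.152), with KO libraries at 0 to 0.23 TPM. It passed with DESeq2 (−6.81 and −8) and with no filter on low counts. Sox11 had folds of −0.63 ± 0.24 and 0.29 ± 0.20 (edgeR, Benjamini-Hochberg adjusted p = 1 for both). Of the Schwann cell and myelin markers in injured ganglia, Prx, a periaxin of myelinating cells, stood at 54 TPM in KO and 119 in WT (log2 fold change −1 ± 0.24), and the 14 genes had a median of −0.27 with 1 lower adjusted over the list alone (camera adjusted p = 0.987 with an estimated correlation). For KO against WT edgeR called 0 genes after sham (133 at an unadjusted p under 0.05, DESeq2 13) and 0 after injury (179 unadjusted, DESeq2 4). For the difference of the responses it also called 0 (104 unadjusted, DESeq2 0). In simulated data of this design 14.9% of genes changed 2-fold and 68.2% of genes changed 4-fold were recovered in the injured comparison of 15204 genes.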

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

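The tests of carry-over, swaps, mixed pools, batch, loss of Silc1, the sham operation and nerve damage in this part were chosen after the results were seen, and the gene length test before.

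A test for a sample far from the others was run on 33 groups and measures (levels of Silc1, Sox11 and Atf3, depth, mitochondrial share, share of the 10 most abundant genes, injury score), of which chance picks about 1 in 20, and it picked 4. Injured WT library 5 of day 4 stood at 25.4 TPM of Silc1 against 11.5 to 12.1 in the 3 others, and at 387 TPM of Atf3 against 284 to 298. Brain KO library 3 stood at 0.34 TPM of Silc1 against 0 to 0.08 in the other KO brains. In day 4 KO sham library 5 the 10 most abundant genes held 24% of the counts against 8.04 to 12.5%, and its mitochondrial share was 9.62%. Between the responses of days 4 and 1, the unannotated transcript MSTRG.6303 differed by a fitted 9.33 on the log2 scale. That number depends on the prior count, since both day 4 shams were listed at 0. It stood at 8.04 to 11.5 TPM in day 1 shams, 2.17 and 2.82 TPM in the injured libraries of day 1, 5.72 to 6.88 TPM in naive ganglia and 0.41 to 2.22 TPM in day 7 shams.

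Silc1 reads were present in 4 of the 10 day 4 ganglion libraries labelled KO. A swap of labels among the day 4 libraries of this series would need WT libraries without Silc1, while the lowest WT library held 2.8 TPM. A swap with a library outside the series, or a wrong label without a swap, could not be tested. Carry-over from injured WT libraries was excluded for the sham libraries KO 1 and KO 3, because it would have brought Sprr1a along, and a share of 0.0208 of the expected Sprr1a was there. Carry-over from sham WT libraries stayed open for KO 3. In TPM, KO 1 stood at a ratio of 1.29 to the WT shams of its set and KO 3 at 0.437. Relative to depth KO 1 did not stand above them, with 78 Silc1 counts in 22 M. WT sham 2 held 56 in 13.1 M and WT sham 3 held 32 in 8.82 M. Carry-over from these WT shams would therefore have to supply most of the reads of KO 1. Their mitochondrial shares were 8.14 and 6.15%, against 2.91% in KO 1, which argues against it for KO 1. From the WT sham of the other set KO 1 would need a share of 0.641 in TPM, where Y-linked genes leave at most 0.231. For the injured libraries KO 1 and KO 3, whose Silc1 stood at a ratio of 0.29 to injured WT, carry-over stayed open because their own Sprr1a is high. Pools that mixed animals with and without an intact Silc1 locus may account for sham KO 3 and injured KO 1 and 3 and stayed open, since other KO libraries held 0 TPM. Sham KO 1 stood above the WT shams of its set in TPM and not in counts. Its pool would need intact animals throughout or nearly so, or intact animals near the level of the WT sham of the other set (ratio 0.641).

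In library set 1 of day 4, 6516 genes differed between KO and WT after sham and 4248 after injury, and 3074 were called in both, 3069 of them with the same sign (1470 for independent lists). Sham and injury libraries of one number may share deviations (r 0.267 to 0.587 in WT and 0.245 to 0.636 in KO, with library set not removed). Neither the 1470 nor the correlation of sham and injury folds allows for this. Loss of Silc1 as the whole cause would recur at day 7 if its effect lasts, since Silc1 was lower in KO there too. The slope of the day 7 folds on the set 1 folds was −0.15, and −0.18 with the level of Y-linked genes as covariate. A recurring effect of the same size gives about 1, or less where noise in the set 1 folds lowers the slope. The 36 assignments of the day 7 libraries reached −0.49 to 0.49, from log CPM differences without that covariate. These slopes go against a lasting effect of that size but cannot exclude a smaller one. Loss of Silc1 acting at day 4 alone stayed open, because set 2 (Pearson r −0.48 with set 1) held 1 WT library per operation and sex went with genotype there (Ddx3y at most 0.08 TPM in WT and at least 3.95 in KO). All 4 libraries labelled KO with Silc1 reads were in set 1, where sham KO 1 held 3.62 TPM against 2.83 and 2.8 in the WT shams. The KO 2 libraries alone held at most 0.05 TPM. The set 1 folds therefore only in part compare libraries without Silc1 to libraries with it. A batch of preparation or sequencing that followed genotype within set 1 may be the source. The sham and injury folds correlated with a Pearson r of 0.66 in set 1 and 0.38 in set 2. A genotype difference present after both operations would give such a correlation too, so it does not tell a batch from the genotype. Gene length stayed open, since the Spearman rho of 0.28 between fold and exonic length lay between the limits set beforehand for and against it. Genes are not independent replicates in any of these values.

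The time course shams of days 4 and 7 held injury genes above naive ganglia, Sprr1a and Atf3 among them. Over 3 genes at day 4, WT shams of the genotype experiment held 1.5, 1.17 and 0.13% of the injured level (median 1.17%). The 2 time course shams held 13 and 4.75% (median 8.88%), there with the naive level subtracted. These shares go against the sham operation as the whole cause at day 4, but so few genes and libraries cannot exclude it. It also stayed open at day 7, where the 2 WT shams of the genotype experiment held 9.64 and 1.34% (median 5.49%). Nerve damage in some sham animals may be the source, and the lowest median share among the 5 sham libraries was 4.75% of the injured rise. Carry-over of reads from injured libraries stayed open too: it needs the same share for every gene, and the 90th percentile was 1.36 times the 10th over 3 genes and 2.12 times over a wider set of 15, whose lowest share was −0.907%. These explanations cannot be told apart with these tables.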

How the results depend on the processing

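The fits without libraries labelled KO that held Silc1 reads, with the Y-linked level as a covariate and with crossed pairs at day 7 were chosen after seeing the data, and the other alternatives before. Over 2549 alternatives for the 195 results of the text, 2104 values stayed on the same side of their threshold with the same sign (205 counts within 1.5 times, 1375 folds, 496 list tests), 14 reversed sign, and in 317 folds and list tests the sign stayed and the call ended. Where no cause is given, the cause was not tested.

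DESeq2 called 713, 558 and 811 genes at days 1, 4 and 7 of the time course, 2981, 470 and 1022 in the shams against naive, and 98 and 20 for the differences between days 4 and 1 and days 7 and 4. It called 4, 2, 22 and 46 with Silc1, Norris1, Sox11 and Atf3 siRNA, 4 in brain, 160 and 74 for KO against WT at day 4 after sham and injury, 747 and 1303 for the WT and KO responses and 4 for their difference. At day 7 it called 13 and 4 for KO against WT and 148 and 147 for the responses. For Silc1 at day 7, DESeq2 gave −6.81 after sham and −8 after injury, past the threshold, as were −6.54 and −7.69 with no filter on low counts. With no filter, edgeR called 2 genes with Sox11 siRNA, 1 and 1 for KO against WT at day 7, and 110 and 130 for the WT and KO responses. RLE scaling gave 19 for the day 7 WT response.

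With only the compared libraries in the fit, and so fewer degrees of freedom, 0, 171 and 161 genes were called at days 1, 4 and 7 and 0, 0 and 1 in the shams against naive. The joint fit with day 4 called 113 and 130 genes for the day 7 WT and KO responses.

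The replicate block changed 6 of 23 counts of genes called, ended the call of 9 of 128 folds and changed 0 of 40 list tests. In the counts it gave 6 genes for day 4 sham against naive, 0 for the difference of days 4 and 1, 1 in brain, 1 for injured KO against WT at day 4, and 8 and 16 for the day 7 WT and KO responses. The crossed pairs of day 7 gave 213 and 219 genes.

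Within library set 1, 1 gene was called in brain, 6516 and 4248 for KO against WT at day 4 after sham and injury, 837 and 1277 for the WT and KO responses and 1 for their difference. Within set 2, 1 gene was called in brain, and 0 and 24 for the WT and KO responses, with fewer libraries. Sox11 reversed to 0.03 in brain and to −0.05 in injured ganglia in set 1. The latter fold follows counts (66.2 CPM in KO and 71.2 in WT), while TPM were higher in KO (30.8 and 20.1), where RSEM gave Sox11 a mean effective length of 3390 bases against 5010. In set 1 the brain list of striatal markers reversed (camera adjusted p = 0.293), and in set 2 those of nociceptor genes (0.00576), macrophage markers (8.18e-06) and interferon-stimulated genes (0.836) in day 4 shams did. These values use the preset correlation, and set 2 held 1 WT sham library, which was assumed to vary like the other groups. With an estimated correlation the 3 lists of set 2 had camera adjusted p-values of 0.783, 0.783 and 0.966.

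Without the 4 libraries labelled KO that held Silc1 reads, 1 gene was called for KO against WT at day 4 after sham and 1 after injury, and 406 for the KO response. Silc1 then passed, with fitted folds of −7.06 and −10.98, of which the second depends on the prior count because the remaining injured KO libraries were at 0. The injury score difference after injury reversed to 0.15. With the Y-linked level as a covariate 1 gene was called after sham. With genes called at both days, the sham injury score difference was 0.

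With each replicate left out in turn, the time course gave 4 to 217, 6 to 345 and 80 to 280 genes at days 1, 4 and 7, 2 to 3108, 3 to 345 and 18 to 678 in the shams against naive at days 1, 4 and 7, and 0 to 4 and 0 to 1 for the differences between days. Sox11 siRNA gave 0 to 0. At day 4 the range was 0 to 2136 for KO against WT after sham, 295 to 377 for the WT and 514 to 926 for the KO response, and at day 7 0 to 6 and 6 to 63. Where a replicate left a group with 1 library, that library was assumed to vary like the other groups. Sox11 with Silc1 siRNA ranged from −0.49 to 1.11 and in injured KO against WT from −0.18 to 0.15, where it reversed in 4 fits (0, −0.07, −0.18 and −0.15). The sham injury score difference ranged from −0.51 to 0.07 and the correlation of Silc1 and Sox11 siRNA folds from 0.19 to 0.29. With 2 controls, simulations without a change gave means of 0.28, 0.29 and 0.31 without controls 1, 2 and 3, against 0.29, 0.22 and 0.21.

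What depth limits was not separated from group size. In simulated data 14.9% of genes changed 2-fold were recovered in the injured comparison of day 7, with 2 libraries per group and a median of 5.57 M counts, and 7.5% with Silc1 siRNA, with 2 and 3 libraries and a median of 23.8 M.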

Other observations

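The counts of other splits of the samples in this part were planned before the results were seen, and the other values were looked at afterwards.

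The seminal vesicle gene Svs4 stood at 912, 49 and 127 TPM in the 3 naive ganglion libraries and between 0.23 and 15.6 TPM in the other 16 time course libraries. Levels of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at a female level in brain WT library 5 and KO library 4, in the day 4 WT injury and WT sham libraries 5, and in the day 7 KO injury and KO sham libraries 2. Among the 5 injured day 4 libraries labelled KO, the injury score was 0.69 and 0.95 in the 2 that held Silc1 reads and 2.27, 2.44 and 2.54 in the 3 without. Of the day 7 WT shams, library 1 held 35.3 TPM of Atf3 and 70.8 TPM of Sprr1a.

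Other splits of the same samples were fitted with the same models. For injury against sham at day 7 of the time course 1 of the 10 splits, the real one, gave as many genes (297, highest other 0), for day 1 sham against naive 1 of 10 (1353, highest other 1), for day 7 sham against naive 1 of 10 (51, highest other 1), and for injured KO against WT in set 1 of day 4 1 of 10 (4248, highest other 1). In these 4 comparisons the splits were too few for a share under 0.05. For day 4 injury against sham, 1 of 35 splits of the WT libraries gave as many genes (464, highest other 2) and 2 of 100 splits of the KO libraries (796, highest other 1750). The KO split with 1750 genes set injured KO library 2 apart and points to a structure of the samples. For the brain, 4 of 100 splits gave at least the 2 genes of the real one, and the highest other gave 2758 by setting WT brain library 3 against the other 5 libraries of its set, which also points to a structure of the samples. Replicate numbers may pair the libraries in the time course at day 7, in brain and in both day 4 responses. In brain and at day 4, number was not told apart from library set. Where numbers do pair the libraries, splits that ignore the pairs do not match these designs. The other splits drawn that parted as many pairs as the real one gave 0 genes in edgeR (3 splits in the time course at day 7, 12 in brain, 7 in day 4 WT and 12 in day 4 KO). At most 4, 16, 8 and 16 such splits exist, the real one included, which are too few for a share under 0.05.

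For KO against WT at day 4, where 0 genes were called by edgeR (2359 and 1741 at an unadjusted p under 0.05, DESeq2 160 and 74), 56 of 56 splits after sham and 100 of 100 after injury gave as many by construction, which says nothing about chance. The highest other split after sham called 4284 genes and followed the mitochondrial share and the genotype of set 1 (KO shams 1 to 4 and WT sham 5 against KO sham 5 and WT shams 2 and 3, whose shares were 9.62, 8.14 and 6.15%). It points to a structure of the samples. The highest other split after injury called 27.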
